A study of Homo sapiens with 6 samples.

How the data were processed

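RNA from 6 samples of H1-derived trophoblast, 3 with control siRNA and 3 with VTCN1 siRNA, was sequenced from Illumina TruSeq stranded mRNA libraries, per the labels' protocols. The transfection lasted 6 h, and RNA was taken 48 h after it. Per the submitters' processing notes, the tools named were cutadapt, Bowtie, TopHat, TopHat2 (version 2.0.13), HTSeq (version 011.1) and Cuffdiff (version 2.2.1), with GRCh38 as the genome build. The role of each tool, the gene annotation and the strand setting of the counting are not given in the sources used here.

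The deposited table was named as a count matrix, but its values were not counts. The deposited values were on a log2 scale: they ran from -2.16 to 18.29, many genes were exactly 0 in every column, and low genes were nearly constant across libraries. This shape is that of a regularised log2 transform, in which low values are pulled towards their mean. How the authors made these log2 values is not given in the sources used here. Library depth could not be recovered, and for that reason no counting interval is given. Of 58522 genes, 22371 were 0 in all columns used. The table also held 5 rows that name no gene. On the unlogged scale, reads without a feature made up 6.42% of the column sum on average, ambiguous reads 7.77% and reads without a unique alignment 5.66%. The other 2 rows made up 3.587e-06% or less. These rows were left out of every step.

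Each column name gave a cell passage, a group, a flow cell and a lane. The lane 1 columns, 1 per passage and group, were taken as the 6 samples. A further 4 columns were not used in any fit or test, since each group then had more columns than samples. By their names these are lane 2 of the passage 53 and 54 libraries. On inspection of the table before the columns were assigned, CUTA, FLOT1 and some other genes disagreed between the lanes of a library. Values of such genes should be doubted. The size of the disagreement and the number of genes affected were not measured, so other named genes may be touched too. The columns carried no replicate number, so the labels' numbers could not be tied to passages. Passage 52 was on another flow cell (2 libraries) than passages 53 and 54 (4 libraries). Nothing in the labels says whether passages were separate experiments, so p-values measure only the spread between these libraries.

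The column names give only a passage number, and whether libraries of a passage shared a culture is not given in the sources used here. Passage was taken as pairing them, which is an assumption. Libraries from a shared culture should deviate together, but across genes their deviations from the group means had correlations of -0.73, -0.60 and -0.63 in passages 52, 53 and 54 (genes are not independent replicates). The effect of removing passage means on the test was therefore simulated, and blocked counts are given beside the main ones wherever they differ. In simulated data for this comparison (16007 genes, 200 of them changed), a fit without the block gave 4.48% false calls when passage means were left in and 71.0% when they were removed. A fit with the block gave 2.62% false calls in the second case. The simulated removal was complete, whereas the deposited values kept some spread of passage means (variance ratio of passage means to differences 0.205). The 71.0% therefore does not estimate the false share of the real calls. Without removal and without the block, 92% of genes changed by 0.5 and 100% of those changed by 1 on the log2 scale were recovered. The changed genes were drawn from those with a mean above log2 of 100, so these rates do not cover weaker tested genes. In simulated lists, drawn at random from genes with independent noise, 1 of 1 shifted list was called, and 0 of the others. Members of real lists can be correlated (camera estimate 0.525 for the interferon list), so this does not check the preset correlation.

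The planned test was a count model, with limma-trend on log2 values as the fallback. As the values were already log2, no pseudocount was added. Genes with a mean of at least 3.32 (log2 of 10) over all 6 libraries were kept, which left 16007. limma 3.58.1 in R 4.3.3 was run with an intensity trend and robust variance estimation, group as the only term, and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of single genes come from this limma fit unless another is named. A fold change is the difference between group means of the deposited log2 values. With 3 libraries against 3, an exact permutation test of 1 gene cannot give a two-sided p below 0.1.

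The 20 gene lists and the rule for naming genes were fixed before the data were examined. The rule takes VTCN1, the 10 largest rises and the 10 largest falls among genes with adjusted p under 0.05 and no overlap between groups, and up to 4 members with the smallest p from each list. Any measured member may be named from the interferon, MHC class I, inflammatory and syncytiotrophoblast lists. Clone-type, antisense and small RNA symbols were left out, and old and new symbols of a gene count once. The rule asked for a minimum mean CPM, which this table cannot give, and the minimum level above stood in for it. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and adjusted over the lists. Labels were also swapped within each passage in turn, and all 10 splits of the 6 libraries were fitted. A group by flow cell interaction was fitted in limma, although the passage 52 flow cell held 1 library per group and added no spread of its own.

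Coordinates and gene types come from GENCODE 29 (GRCh38) by symbol, which matched 14455 of 16007 tested genes (90.3%). The alternatives tried were no filter, a minimum of log2 of 100, no robust estimation, no trend, each library left out, a passage block, passages 53 and 54 only, quantile normalisation, equal column sums, and the table without MHC-region and pseudoautosomal genes.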

Results

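Gene expression was measured by RNA sequencing in trophoblast made from H1 (WA01) cells, an established human embryonic stem cell line. The cells were differentiated with BMP4 (10 ng/mL), the TGF-beta receptor inhibitor A83-01 (1 µM) and the FGF receptor inhibitor PD173074 (0.1 µM), a combination known as BAP. On day 3 they received 10 nM of either a scrambled control siRNA or an siRNA duplex against VTCN1 (B7-H4), an inhibitory member of the B7 family of immune checkpoint ligands. RNA was taken 48 h after transfection, on day 5, for 3 control and 3 knockdown libraries, 1 of each from cell passages 52, 53 and 54. Earlier and later time points named in the study's design were not analysed here. The deposited values were already on a log2 scale, so the sequencing depth of each library was unknown. Low values looked shrunken towards their mean, so folds of weakly expressed genes may be understated. The question was which genes changed with the knockdown, with trophoblast differentiation, proinflammatory responses and MHC class I named as its subjects in the study's title.

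VTCN1 itself was lower in each knockdown library. Its deposited log2 value was 13.14, 13.11 and 13.11 in the controls of passages 52, 53 and 54, against 11.19 in the knockdown library of passage 52 and 11.01 or lower in those of passages 53 and 54. The mean fell from 13.12 ± 0.01 (SD, n = 3) to 11.07 ± 0.10 (SD, n = 3), a log2 fold change of -2.05 (SE 0.05; limma adjusted p = 3.851e-06), which left 24.1% of the control level. VTCN1 lies on the minus strand of chromosome 1 at 117143587 to 117210960 (GENCODE 29, GRCh38). Its difference was -1.95 in passage 52, whose libraries were on a different flow cell, and -2.10 and -2.11 in passages 53 and 54.

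Interferon-stimulated genes made up most of the large changes after the knockdown. Of 38 genes that changed at least 2-fold, 36 rose, and 20 of these belonged to the list of interferon response genes. Only VTCN1 and SPP1 fell by that much. The 38 genes moved in the same direction in all 3 passages, but so did every gene called at any size, so direction does not set them apart. With passage as a block 37 of the 38 passed, the exception being CD99 (adjusted p = 0.101). Below 2-fold the calls were far less firm. In all, 1207 genes rose and 1386 fell among 16007 tested (limma, adjusted p under 0.05), and 2000 of these 2593 calls were changes of less than 1.2-fold. With passage as a block, 302 genes rose and 324 fell, all of them among the 2593. When the labels were swapped within passage 52 alone, 979 genes passed without the block and 0 with it (limma, adjusted p under 0.05; 1613 with the block at an unadjusted p under 0.05). Leaving out any 1 library of passages 53 or 54 lowered the 1207 rises to between 727 and 753.

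Within the flow cell that held passages 53 and 54, at 2 libraries per group, 1465 genes rose, 1375 fell and 40 changed at least 2-fold, and 37 of the 38 genes above passed. The other flow cell held 1 library of each group, so only differences could be taken there. A limma interaction called 370 genes between the flow cells (adjusted p under 0.05), and for 354 of these passage 52 went the opposite way from passages 53 and 54. Its spread came from passages 53 and 54 alone, so 1 unusual library of passage 52 is enough for a call, and these p-values do not show a difference between flow cells. CYP1B1, a cytochrome P450, differed by -0.56 in passage 52 and by 0.67 and 0.66 in passages 53 and 54. PLIN2, a lipid droplet coat protein, differed by -0.44 in passage 52 and by 0.52 and 0.53 in the others. Both were chosen after their values were seen, and neither passed the test over all 3 passages.

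**Figure D1:**
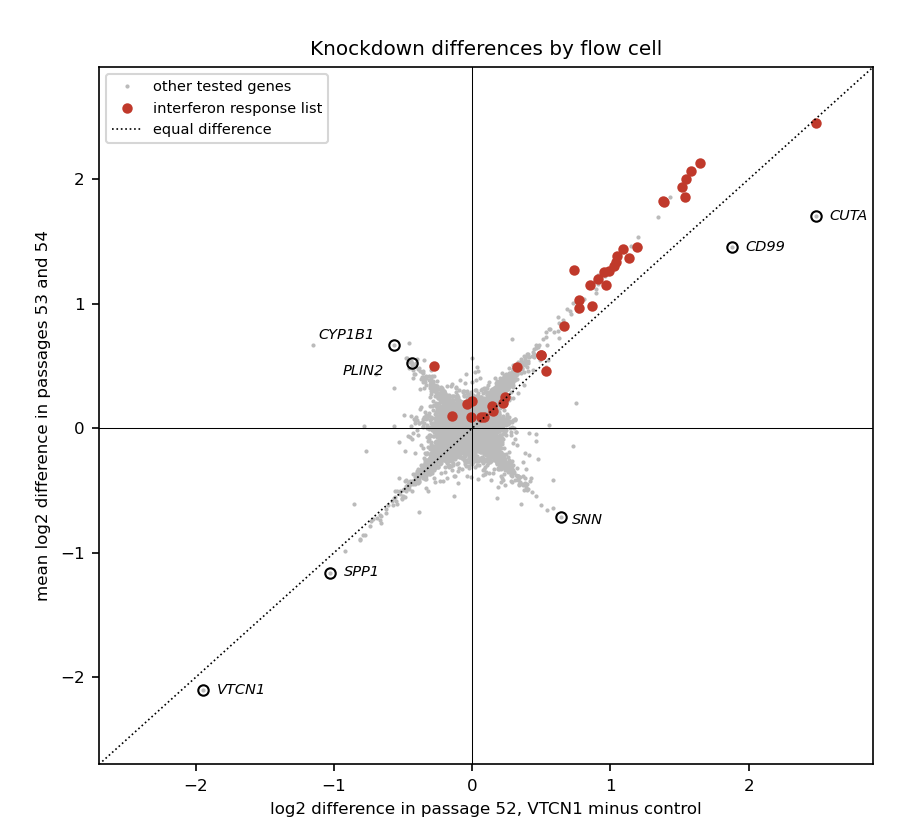
Each point is 1 tested gene, with its log2 difference between the VTCN1 siRNA and control siRNA libraries of passage 52 (x axis) and the mean of that difference in passages 53 and 54 (y axis). Members of the interferon response list are red, the dotted line marks equal differences, named genes are circled and HBB (x = 6.84) lies outside the axes. VTCN1, SPP1 and most interferon genes differ in the same direction on both flow cells, while CYP1B1 and PLIN2 lie on the opposite diagonal.

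The 10 genes with the largest rises were led by OAS2, an antiviral 2'-5' oligoadenylate synthetase, on chromosome 12 at 112978395 to 113011723. Its log2 value went from 8.09 ± 0.09 (SD, n = 3) to 10.55 ± 0.06 (SD, n = 3), a log2 fold change of 2.46 (SE 0.05; limma adjusted p = 2.162e-06). BST2, which tethers budding virus to the cell surface, rose by 1.97 (SE 0.09), and MX1, an antiviral GTPase, by 1.91 (SE 0.09). OAS3 rose by 1.85, IFIT1 by 1.80, IFIT3 by 1.75, IFITM1 by 1.71, IFI6 by 1.68 and ISG15, a ubiquitin-like protein, by 1.67 on the log2 scale. IFITM1 has close paralogs, so reads shared with them make its value uncertain. For these 9 genes the adjusted p was 2.749e-05 or lower, and 0.00267 or lower with passage as a block. CUTA also rose by 1.97 (SE 0.14; limma adjusted p = 0.000156), with differences of 2.48, 1.68 and 1.73 in the 3 passages. CUTA lies at 33416442 to 33418317 on chromosome 6, inside the extended MHC region in which most genes were listed at or near 0, so its value is uncertain. On inspection of the table CUTA also disagreed between the lanes of a library, and its rise should be doubted. CD99, a pseudoautosomal gene named after its values were seen, differed by 1.88, 0.33 and 2.58, and its call was lost under most alternative settings.

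**Figure D2:**
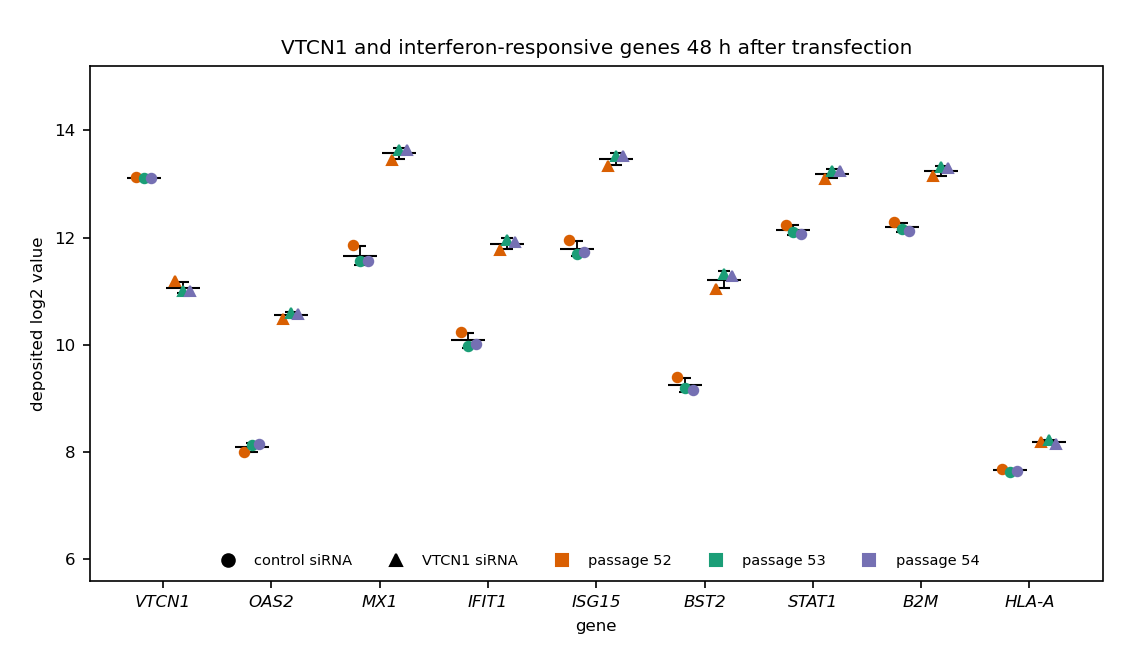
Deposited log2 value (y axis) of VTCN1 and 8 interferon-responsive genes in each library, with circles for control siRNA, triangles for VTCN1 siRNA and colours for the cell passage. Black bars are the mean ± SD of the 3 libraries of a group. VTCN1 falls from 13.12 to 11.07 and OAS2 rises from 8.09 to 10.55, with no overlap between groups for any gene shown.

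The largest falls after that of VTCN1 were in genes of varied function. SPP1 (osteopontin, a secreted matrix phosphoprotein) went from 12.29 ± 0.0035 (SD, n = 3) to 11.17 ± 0.07 (SD, n = 3), a log2 fold change of -1.12 (SE 0.04; limma adjusted p = 1.665e-05). BCAT1, the cytosolic branched-chain aminotransferase, fell by 0.96, OXTR, the oxytocin receptor, by 0.87 and IGFBP5, an insulin-like growth factor binding protein, by 0.86. TNFSF15, a TNF superfamily cytokine, and SFN, the 14-3-3 sigma protein, each fell by 0.83. PHOSPHO1, a phosphatase of bone mineralisation, fell by 0.74 and CA3, a carbonic anhydrase, by 0.73. RPL27A, a ribosomal protein gene, fell by 0.77, although ribosomal protein genes have many processed pseudogenes that can take their reads. All of these passed with passage as a block, at adjusted p of 0.00325 or lower.

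Gene lists fixed before the data were examined were tested next. Of 20 lists, 18 had at least 5 tested members, and camera with a preset correlation called 7, of which 6 were higher and 1 was lower. None of the 18 passed with an estimated correlation (camera, lowest adjusted p = 0.244; 3 at an unadjusted p under 0.05). Other groupings of the 6 libraries gave up to 11 called lists. Each other grouping keeps most knockdown libraries on the same side, so it holds part of the real difference and gives no null.

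Most interferon response genes rose. Of 39 tested members, 33 rose and none fell, with 36 rising when p was adjusted over the list alone and 30 with passage as a block. The median member was 2.07-fold higher (camera adjusted p = 1.141e-35, and adjusted p = 0.244 with an estimated correlation). The median difference was 0.85 in passage 52 and 1.13 and 1.12 in passages 53 and 54. STAT1, the transcription factor that carries interferon signals to the nucleus, rose by 1.05 (SE 0.06), and IRF7, which drives type I interferon transcription, by 0.94 (SE 0.05). The viral RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) rose by 1.27 and 1.24. The 6 members that did not pass were STAT2 (0.14), RSAD2 (0.02), ISG20 (0.24), GBP2 (0.12), IFI44L (0.15) and TLR3 (0.06). IRF9 rose by only 0.09 and lost its call with passage as a block (limma adjusted p = 0.172). Interferons themselves were near the floor, too low for a difference to be seen on a scale that looked shrunken. IFNB1 lay between 1.41 and 1.43 and IFNL1 between 2.82 and 2.89 in the 6 libraries. The list was also called in 8 of the 9 other splits of the libraries (camera, lowest adjusted p = 3.584e-09). Among them was a swap of labels within 1 passage (adjusted p = 0.000849). Part of the real difference remains in each of these splits, so calls there are no measure of chance.

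**Figure D3:**
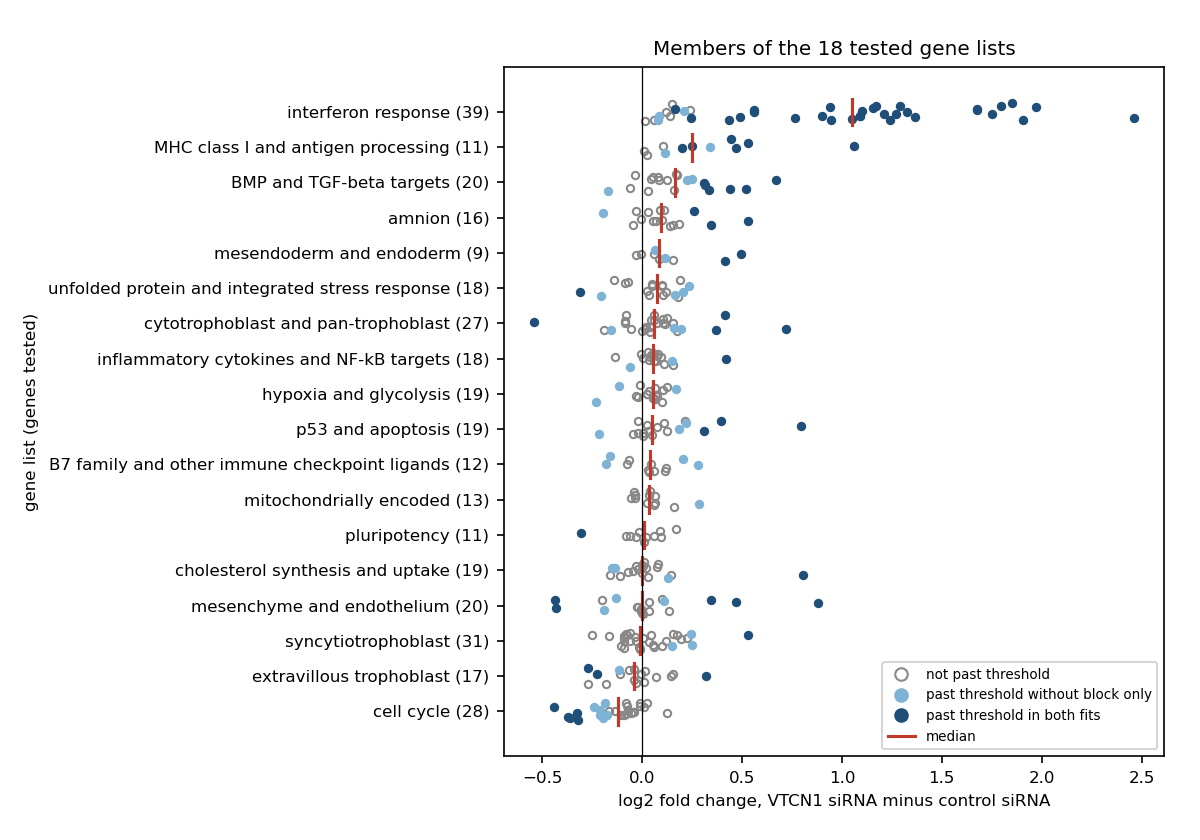
Log2 fold change (x axis, VTCN1 siRNA minus control siRNA) of each tested member of the 18 lists with at least 5 tested genes, with the number tested in brackets. Dark points passed an adjusted p of 0.05 with and without passage as a block, light points only without it, open points in neither, and red lines are list medians. The interferon list has a median of 1.05, and the next highest is the MHC class I list at 0.25.

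Of the MHC class I and antigen processing genes that could be measured, most rose. Of 11 tested members 8 rose, none fell and 3 did not pass, with the same 8 and 0 adjusted over the list alone and 6 with passage as a block (camera adjusted p = 3.189e-07, and adjusted p = 0.244 with an estimated correlation). The list was also called in 4 of the 9 other splits (lowest adjusted p = 0.000769), among them a swap of labels within 1 passage (adjusted p = 0.0296). B2M, the light chain of class I molecules, rose from 12.19 ± 0.09 (SD, n = 3) to 13.25 ± 0.09 (SD, n = 3), a log2 fold change of 1.06 (SE 0.06; limma adjusted p = 4.860e-05). HLA-A rose by 0.53 (SE 0.03), the proteasome activator PSME2 by 0.47 (SE 0.04) and ERAP1, which trims peptides for class I loading, by 0.45 (SE 0.04). HLA-G, the class I molecule typical of extravillous trophoblast, had log2 values of 5.43 in controls and 5.44 after knockdown and did not pass. HLA-B, at 3.33 and 3.36, did not pass either. The 7 untested members all lie in the MHC region of chromosome 6. Of these TAP1, TAP2, PSMB8 and PSMB9 were listed at 0 in all 6 libraries, and HLA-E, HLA-F and TAPBP were below 1.

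Low values in that region were not limited to immune genes. In the extended MHC region, taken here as the protein-coding genes from 28503296 to 33457548 on chromosome 6 (GENCODE 29, GRCh38), 155 of 173 genes (89.6%) were below the minimum level and 118 were listed at 0 throughout. In the flanking 5 Mb on either side, 61 of 164 (37.2%) were below it. RPS18, a protein of the small ribosomal subunit, had a mean log2 value of -1.87, whereas RPS3 was at 15.16 and RPS5 at 13.91. Classical class I heavy chains share sequence with each other as well, so HLA-A, HLA-B and HLA-C values are uncertain. HLA-G lies in the same region, so its value and its lack of a change are uncertain too. The class I heavy chain response could not be fully read from this table.

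**Figure D4:**
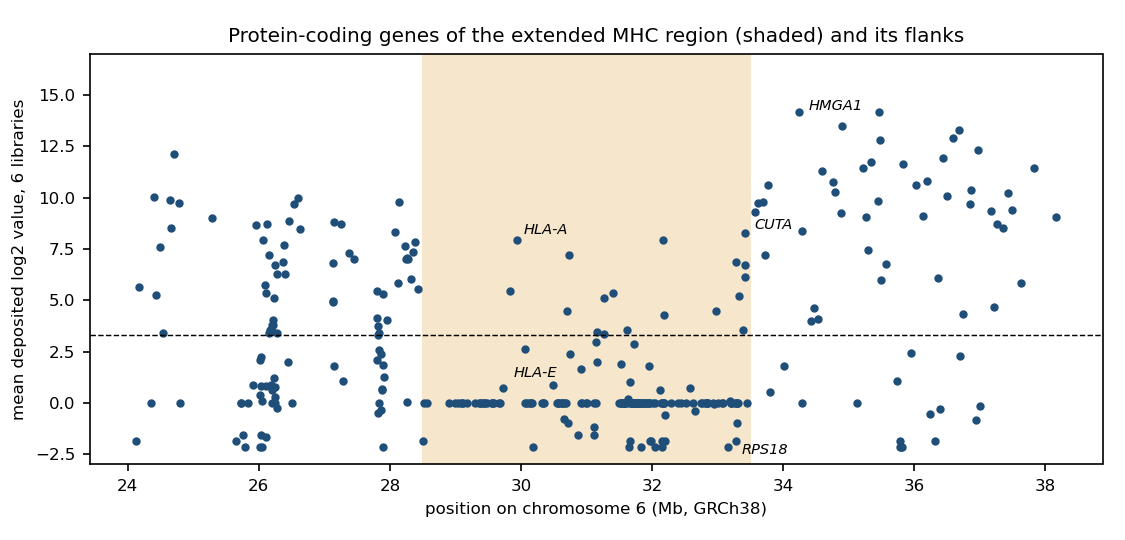
Mean deposited log2 value over the 6 libraries (y axis) of each protein-coding gene by its start on chromosome 6 (x axis, Mb, GRCh38), with the extended MHC region shaded and the minimum level for testing dashed. Of 173 genes in the shaded region 155 lie below the line, against 61 of 164 in the flanks.

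Inflammatory cytokines and NF-kB targets were not called as a list over all 3 passages. Of 18 tested members 2 rose and 1 fell, with 2 and 1 adjusted over the list alone, and 1 rise and 0 falls with passage as a block (camera adjusted p = 0.0725). CSF1, the macrophage colony-stimulating factor, rose by 0.42 (SE 0.04; limma adjusted p = 0.000442). NFKB1 rose by 0.15 and CXCL5 fell by 0.06, and neither passed with passage as a block (adjusted p = 0.221 and 0.117). The NFKB1 call was also lost without any 1 of the 6 libraries, with log2 fold changes of 0.12 to 0.17. TNFAIP3, an NF-kB-induced feedback inhibitor, had a log2 fold change of 0.11 (SE 0.06; limma adjusted p = 0.330), and IL6 one of 0.04 (SE 0.05; limma adjusted p = 0.680). Within passages 53 and 54 alone, 9 members rose and none fell (camera adjusted p = 0.000126, and adjusted p = 0.184 with an estimated correlation), and 8 of the 9 were lower in passage 52. TNFAIP3 rose there by 0.22 (adjusted p = 0.0128), TNFAIP2 by 0.38 (0.00384), RELB by 0.23 (0.0165) and CCL5 by 0.21 (0.00741), with differences of -0.10, -0.30, -0.18 and -0.20 in passage 52. The median member differed by -0.09 in passage 52 and by 0.11 and 0.15 in passages 53 and 54. TNF, in the MHC region, was listed at 0, and CXCL10 and CXCL11, chemokines that interferon usually induces, were at the floor in all 6 libraries.

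Syncytiotrophoblast genes were not called as a list over all 3 passages. Of 31 tested members 4 rose and none fell, with 4 and 0 adjusted over the list alone and 1 and 0 with passage as a block (camera adjusted p = 0.359). Within passages 53 and 54 alone 8 rose and none fell (camera adjusted p = 0.0415, and adjusted p = 0.674 with an estimated correlation), and 4 of the 8 were lower in passage 52. CRH, the placental stress peptide hormone, rose by 0.53 (SE 0.04; limma adjusted p = 0.000195). CYP19A1 (aromatase) rose by 0.25, HSD11B2, which inactivates cortisol, by 0.25 and ERVFRD-1 (syncytin-2) by 0.15, and these lost the call with passage as a block (adjusted p = 0.0754, 0.0609 and 0.186). The ERVFRD-1 call was also lost without any 1 library of passages 53 or 54, at 0.13 to 0.16. CGA, the alpha subunit of chorionic gonadotropin, had log2 values of 15.90 ± 0.25 (SD, n = 3) in controls and 15.81 ± 0.21 (SD, n = 3) after knockdown. It differed by -0.36 and -0.35 in passages 52 and 53 and by 0.44 in passage 54. The median member of the list likewise differed by -0.09, -0.09 and 0.25 in passages 52, 53 and 54. Passages 53 and 54 thus did not agree on the list, and only 4 members were higher and 2 lower in all 3 passages. The fusion regulator GCM1 had a log2 fold change of -0.09 (SE 0.03; limma adjusted p = 0.0895).

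Other trophoblast lists moved in part. Of 27 tested cytotrophoblast and pan-trophoblast genes 5 rose and 2 fell, or 8 and 2 adjusted over the list alone and 3 and 1 with passage as a block (camera adjusted p = 0.0386, and adjusted p = 0.392 with an estimated correlation). The list call was lost without the passage 53 control (adjusted p = 0.0533) or the passage 54 knockdown library (0.0678). The counts were 10 rises and 5 falls in passages 53 and 54 alone. HAND1, a transcription factor of early extraembryonic lineages, rose by 0.72 (SE 0.05), KRT7, a trophoblast keratin, by 0.42 and MSX2, a homeobox factor induced by BMP, by 0.37. ITGA6, the laminin-binding integrin of cytotrophoblast, fell by 0.54 (SE 0.04). Of 17 extravillous trophoblast genes 1 rose and 3 fell, with the same counts adjusted over the list alone and 1 and 2 with passage as a block (camera adjusted p = 0.359). The fibronectin receptor chain ITGA5 rose by 0.32, and ITGA1 and PLAC8 fell by 0.27 and 0.22. Of 16 amnion genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0544), with 3 and 0 and a camera adjusted p of 0.0307 with passage as a block. In passages 53 and 54 alone 6 amnion genes rose and 1 fell (camera adjusted p = 0.00543, and adjusted p = 0.230 with an estimated correlation). Over all 3 passages IGFBP3 led the amnion genes at 0.53.

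Some BMP and TGF-beta target genes rose. Of 20 tested members 8 rose and 1 fell, both over all genes and adjusted over the list alone, and 6 rose with passage as a block (camera adjusted p = 0.000275, and adjusted p = 0.586 with an estimated correlation). The BMP-induced inhibitors of differentiation ID1, ID2 and ID3 rose by 0.67, 0.52 and 0.44, and the feedback inhibitor SMAD6 by 0.33. Of the 20 members 13 rose and none fell in passages 53 and 54 alone, and 5 of the 13 were lower in passage 52. The median member differed by 0.16 in passage 52 and by 0.29 and 0.35 in passages 53 and 54.

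Some cell cycle genes fell. Of 28 tested members 12 fell, 16 did not pass and none rose, with 13 and 0 adjusted over the list alone and 5 falls with passage as a block (camera adjusted p = 4.945e-08, and adjusted p = 0.244 with an estimated correlation). The mitotic kinase AURKA fell by 0.44 (SE 0.03), the replication helicase subunit MCM6 by 0.37 (SE 0.03), CDK1 by 0.33 and the spindle checkpoint kinase BUB1 by 0.32. The falls were modest, at a median of -0.12 over the list. Of 19 p53 and apoptosis genes 5 rose and 1 fell, or 6 and 1 adjusted over the list alone and 3 and 0 with passage as a block (camera adjusted p = 0.0204, and adjusted p = 0.861 with an estimated correlation). ZMAT3, a p53 target, rose by 0.80 (SE 0.05), the pro-apoptotic BCL2L11 by 0.40 and GDF15 by 0.31. In passages 53 and 54 alone, 8 of the 19 rose and 1 fell. The p53 call was lost without either library of passage 54 (adjusted p = 0.0686 without the control and 0.101 without the knockdown library). The p53 list was also called in 3 of the 9 other splits, and a swap of labels within 1 passage gave an adjusted p of 0.000849, lower than that of the real labels. The cell cycle and BMP lists were each called in 5 of the 9 other splits. A swap of labels within 1 passage gave camera adjusted p as low as 1.202e-05 for the cell cycle list and 0.000797 for the BMP list.

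Markers of other lineages were tested as well. Of 9 mesendoderm and endoderm genes 4 rose and none fell, also adjusted over the list alone, and 2 with passage as a block (camera adjusted p = 0.0124, and adjusted p = 0.392 with an estimated correlation), led by APOB at 0.49 and KDR, a VEGF receptor, at 0.41. The list was also called in 1 of the 9 other splits. Of 20 mesenchyme and endothelium genes 4 rose and 4 fell, also adjusted over the list alone, and 3 and 2 with passage as a block (camera adjusted p = 0.956). The collagens COL6A3 and COL1A1 rose by 0.88 and 0.47, while CDH5 and LUM each fell by 0.43. Of 11 pluripotency genes 1 fell, LIN28B by 0.30, and none rose, with the same counts adjusted over the list alone and with passage as a block (camera adjusted p = 0.956). Of 4 neural genes 1 rose, and of 3 leukocyte genes 1 rose, with 2 and 1 adjusted over the list alone. None of either passed with passage as a block. The counts in passages 53 and 54 alone were 1 rise and 3 falls for pluripotency and 2 rises for neural genes.

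The remaining lists were not called over all 3 passages. Other B7 family and checkpoint ligands gave 2 rises, CD276 (B7-H3) by 0.28 and NECTIN2 by 0.20, and 2 falls, the complement regulators CD59 by 0.16 and CD46 by 0.18, among 12 tested members (camera adjusted p = 0.448). The counts were the same adjusted over the list alone, and none of the 4 passed with passage as a block. CD46 also lost its call without the knockdown library of passage 52 (-0.16) or 53 (-0.16) or the control of passage 54 (-0.17). Of 19 cholesterol genes 2 rose, led by SC5D at 0.80, and 2 fell, or 2 and 3 adjusted over the list alone and 1 and 0 with the block (camera adjusted p = 0.956), and 4 and 1 in passages 53 and 54 alone. Of 18 unfolded protein and integrated stress response genes 3 rose and 2 fell, or 4 and 2 adjusted over the list alone and 0 and 1 with the block (camera adjusted p = 0.359). Of 19 hypoxia and glycolysis genes 1 rose and 2 fell, and of 13 mitochondrially encoded genes 1 rose, with the same counts adjusted over the list alone. None of these passed with the block (camera adjusted p = 0.359 and 0.448). Within passages 53 and 54 alone camera called 3 of these lists: the unfolded protein list with 7 rises and 2 falls (adjusted p = 0.00543), hypoxia with 6 and 1 (0.0155) and the mitochondrial list with 3 and 0 (0.0332). All 3 calls were lost with an estimated correlation (adjusted p = 0.496, 0.234 and 0.674). The median mitochondrial member differed by -0.17, -0.15 and 0.29 in passages 52, 53 and 54, so passages 53 and 54 went opposite ways.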

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

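The passage block, the restriction to passages 53 and 54, the 2 scalings, the stricter filter, the fit without a trend and the table without MHC-region and pseudoautosomal genes were chosen after seeing the data. The knockdown of VTCN1 and the count of genes changed at least 2-fold (36 to 40 over all settings) kept their direction and stayed within 1.5 times the reported value under all of them. The 20 named genes with the largest changes passed in each fit, except that CUTA was removed with the MHC-region genes. Pairing moved the gene counts most: with the passage as a replicate block 302 genes rose and 324 fell, in place of 1207 and 1386, and the block changed no list call except to add amnion. Leaving out 1 library gave between 727 and 938 genes higher, between 942 and 1024 lower, 36 to 38 at 2-fold, 5 to 9 lists and a VTCN1 log2 fold change between -2.11 and -2.02. The lowest count of higher genes, 727, came without the passage 54 control, and 730, 737 and 753 came without the passage 53 control, the passage 53 knockdown and the passage 54 knockdown library, with 2 libraries left in that group. Lists called numbered 0 with an estimated correlation, 6 with fry and 13 in passages 53 and 54 only, against 7. The cause of the last was not tested. The cytotrophoblast call was lost without the passage 53 control (adjusted p = 0.0533), without the passage 54 knockdown library (0.0678) and with the stricter filter (0.0512), over a range of 0.00826 to 0.392 across its alternatives, and the p53 call with camera ranged from 0.000290 to 0.861. With fry, which tests a list against no change and not against other genes, the p53 list had an adjusted p of 0.103. CGA reversed to a log2 fold change of 0.047 in passages 53 and 54 only. The mesendoderm list had too few members for a value under the stricter filter. Count-model, voom, library-size and pseudocount alternatives were not run, since the values were not counts and were already logged. A mean of 10, planned as an alternative filter, became the main one. Depth limits are unknown, and the apparent shrinkage may hide changes of low genes.

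Among the 10 splits of the 6 libraries, the real one gave 1207 higher and 1386 lower genes and the highest of the others 512 in a direction, from the split that swaps the flow cell of passage 52, where the block gave 0 calls. For 2-fold changes the values were 38 and 0. In each of these 3 results 1 of the 10 splits, the real one, was as large. For lists 6 of the 10 splits called as many, and the highest other called 11 against 7. Every other split keeps most knockdown libraries on the same side, so its calls hold part of the real difference. With 10 splits no share under 0.05 can be had. Of the splits that part all 3 passages, the other 3 called 979, 0 and 46 genes.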

Other observations

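All tests below except the one on chromosome 19 genes were chosen after the result was seen. Several of the genes that rose most lay outside the fixed interferon list, and those named here were chosen after their values were seen. UBE2L6, the conjugating enzyme for ISG15, rose by 1.58 (SE 0.07), the nuclear body protein SP100 by 1.42 (SE 0.07), the lysosomal transporter SLC15A3 by 1.37 (SE 0.05) and SAMHD1, which depletes nucleotides needed by viruses, by 1.36 (SE 0.07). The secreted glycoprotein LGALS3BP rose by 1.27 (SE 0.06). Each was higher in all 3 passages, with limma adjusted p of 2.749e-05 or lower and 0.00267 with passage as a block.

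Of the 354 genes that went opposite ways on the 2 flow cells, those named here were chosen after their values were seen, and passage 52 gives a single difference for each. TNFRSF10B, a death receptor, differed by -0.44 in passage 52 and by 0.52 and 0.57 in passages 53 and 54, the stress-induced CHAC1 by -0.36, 0.48 and 0.43, and the activin subunit INHBA by -0.31, 0.42 and 0.42. The amino acid transporter SLC7A5 went the other way, at 0.36, -0.46 and -0.44. HBB is not among the 354, since its differences in passages 53 and 54 had opposite signs (-0.08 and 0.05). Its large passage 52 difference came from 1 library. HBB stood at 12.59 in the passage 52 knockdown library and between 5.75 and 6.01 in the other 5, while HBA1 was at 3.64 there and 3.24 to 3.25 elsewhere.

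The rise of interferon response genes is the clearest pattern in the table. An effect of 1 passage or flow cell as the whole cause is argued against by the direction of the differences. Of the 39 tested members 35 were higher in all 3 passages and none was lower in all 3. Among all genes 35.2% moved the same way in 3 passages. The lowest passage median was 0.85, above 0.35, the highest passage median of any other tested list. Scaling of each passage to a common spread could alter such sizes but not directions, so the medians alone do not settle it. The rise was smaller in passage 52, at a median of 0.85 against 1.13 and 1.12 in passages 53 and 54. Removal of passage means as the whole cause is argued against too, since it leaves differences within a passage as they are, and 30 of the 33 members that rose passed with passage as a block, against 626 of 2593 genes overall. A response to the duplex itself, through RNA sensors or an unintended target, cannot be told apart from a response to lower VTCN1, because the labels name 1 VTCN1 duplex and it is present in each knockdown library and in no control. Both therefore remain candidate explanations, and scaling of each passage to a common spread stays open for the sizes and p-values.

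How the values were prepared is a candidate explanation for the many small changes called without a passage block. If passage means were removed before deposit, the 2 libraries of a passage would deviate in opposite directions. Across genes their correlations were negative in each passage, at -0.60 or lower. Complete removal from the 6 columns used would leave no spread of passage means, but some was kept (variance ratio of passage means to differences 0.205). The ratio rests on the lane 1 columns alone, and removal over all columns of a passage could leave some spread in them. Removal, complete or partial, therefore remains open. If each passage was also scaled to a common spread, genes whose direction differs would still have matching sizes. Among genes with a mean difference of at least 0.3 in passages 53 and 54, 187 went the opposite way in passage 52. Only 13.4% of these had a passage 52 difference under 0.5 times that mean (median ratio 0.80). All 2593 genes called without the block moved the same way in 3 passages, so none of the 187 was among them. The match in size is therefore only indirect for the called changes. The 532 genes of unchanged direction matched about as well (7.89%, median ratio 0.75), and over all genes the smallest difference was a median 0.39 of the largest, against 0.225 for random differences. A real difference in response between passages is a biological explanation that was not tested. For changes of at least 2-fold the tables argue against removal of passage means as the source, since 37 of 38 passed with passage as a block. Concordance rose with size, from 35.2% of all genes moving the same way in 3 passages (25% by chance). It reached 97.6% of those with a median difference of at least 1. Removal leaves the sign of a difference within a passage as it is, so this concordance cannot test removal.

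Most genes of the extended MHC region were at or near 0, and that they are simply off is argued against by 5 region members of universal complexes (RPS18, VARS, PFDN6, LSM2 and CSNK2B), whose median log2 value was 0, below the lowest of 24 partner genes elsewhere at 8.93. Reads shared with alternate copies in the reference were a candidate cause, and the leukocyte receptor complex on chromosome 19, which also has such copies in GRCh38, was expected to be low as well. It was not: 0 of 7 widely expressed genes there lay below the minimum level, and RPS9 was at 14.81. This argues against alternate copies in general only if the reference used held the chromosome 19 copies, which the sources used here do not state. Alternate copies of the MHC region alone, or another step that affected that region alone, remain open and were not tested. CUTA, HLA-A and HLA-G, in this region, may therefore rest on part of their reads, and CUTA also disagreed between lanes.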
